A study of Mus musculus with 2 samples.

How the data were processed

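Single-cell RNA sequencing was performed on sorted cells of the adult mouse brain, with 1 library per genotype and 2 libraries in all. Per the labels, the sort took mural cells and fibroblasts through CD13 or CD140a without O4, endothelial cells through CD31, astrocytes through ACSA-2, border-associated macrophages (BAMs) through high CD11b with F4/80, and microglia through CD11b with high F4/80. Per the labels, libraries were made on the 10x Chromium platform with the Next GEM 3′ v3.1 chemistry, in which each molecule is read from its 3′ end and carries a unique molecular identifier (UMI).

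The deposited matrices hold raw UMI counts per gene and cell barcode, integers with no normalisation. Per the file headers they were written by Cell Ranger 7.1.0. The submitters' processing notes name Cell Ranger and the builds GRCm38.p6 and mm10. The aligner settings, intron counting, cell calling and any correction for free RNA are not given in the sources used here. The matrices list 26033 genes, and 25637 of their identifiers were matched to the GENCODE annotation of GRCm38, from which gene locations were taken. Read files, images and other assays of the study were not used here. No deposited cell annotation was used, so cell classes were rebuilt and can differ from those of the study.

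Barcodes with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. Doublets were called per library with Scrublet in scanpy 1.11.5 at an expected rate of 0.008 per 1000 barcodes and its automatic threshold, which marked 2.46% of control and 2.31% of mutant barcodes, and these were removed. Counts of both libraries were scaled to 10000 per cell, log-transformed and reduced to 2000 variable genes and 30 principal components, without sex-linked or mitochondrial genes and without integration. Leiden clustering with 15 neighbours at resolution 1 gave 24 clusters. A cluster was named from markers fixed beforehand when at least 3 of them were detected in at least 25% of its cells, at 25% or more of the CPM of the highest cluster, and no other class competed. Clusters with markers of another class, with low depth and no own marker among their leading 10 genes, or with under 3 markers stayed unnamed. The thresholds of this naming rule were revised after a first naming, with its cluster sizes per library and leading genes, had been seen and before any gene was compared. The first rule asked that a marker reach 3 times its median CPM over clusters and ranked leading genes without the 25% minimum. It gave the same microglia-like, BAM-like, endothelial-like and oligodendrocyte-like cells. It left astrocyte clusters 5 and 7, fibroblast cluster 21 and the choroid plexus epithelium-like, ependymal-like and erythroid-like clusters unnamed, and it named cluster 19 as astrocyte and cluster 22 as neuron. Results on astrocyte-like, choroid plexus epithelium-like and ependymal-like cells, and on cluster 21, thus rest on the revised rule. Classes are written as "X-like" to mark that they rest on RNA alone.

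UMIs were summed per class and library and divided by the class total to give CPM, the UMIs of a gene per 1000000 UMIs of the class. With 1 library per group no test between genotypes exists, so there is no p-value. All intervals cover counting error only, not the spread between animals, and those of CPM and ratios do not cover the spread between cells. Shares carry exact Clopper-Pearson 95% intervals, CPM carry exact Poisson 95% intervals, and the mutant to control ratio of CPM carries the exact conditional 95% interval for a pair of Poisson counts. A gene with at least 50 UMIs in a class over both libraries was measured. It met the size rule when its ratio was at least 1.5, or at most the inverse, with an interval that excluded 1. Mitochondrial, ribosomal protein, predicted, haemoglobin and sex-linked genes were left out of the rule, and genes below 10% of their CPM in another named class were counted apart because free RNA reaches all droplets. RNA of unnamed clusters was not screened in this way, so the prolactin gene Prl, held mainly by unnamed cluster 3, entered the rule. A gene with 0 UMIs in 1 library is given as an at least N-fold difference against a floor of 3 counts. Classes with under 50 cells in a library gave no gene count, except that ependymal-like cells, with 48 in the control, were described beside choroid plexus epithelium-like cells as classes added after the data were seen.

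Named genes followed a rule: per class, the 10 with the highest and the 10 with the lowest interval bound nearer to 1 among genes that met the size rule at 20 CPM or more in 1 library, CSF1R with its ligands, and the 2 to 4 members of each described list that differed most. Genes named outside this rule are said to be, and a few genes that met it are not reported here. For 40 fixed gene lists the median log2 ratio (CPM plus 1) of the measured members was set beside 10000 random lists of the same size matched on expression within the class. A list with fewer than 3 measured members gave no median. The percentile is a description of these libraries, and a list is said to lie below or above its random lists outside their middle 95%. The cell filter, markers, clustering, size rule, gene lists and most alternative settings were fixed before the data were examined, and the thresholds for naming clusters were not.

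The ratio and list calculations were tested on simulated counts drawn from the pooled libraries with 200 altered genes per class. Of genes altered 2-fold, 83.6% met the rule in endothelial-like, 92.5% in fibroblast-like, 89.6% in astrocyte-like, 98.5% in microglia-like and 91.0% in BAM-like counts. Of genes altered 4-fold, 72.7% were found in endothelial-like counts because lowered genes fell under 50 UMIs, and 100% of those still measured were found. Intervals held the true ratio for 95.3% to 96.3% of genes. The counts were drawn from the Poisson model that the intervals assume, so this coverage was largely fixed by the design. Counting error alone made unaltered genes meet the rule, 133 in endothelial-like, 153 in fibroblast-like, 132 in astrocyte-like, 51 in microglia-like and 150 in BAM-like counts. The filter on other classes was not applied there. Spread between cells was not simulated, so real cells can give more such genes.

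The alternative settings chosen beforehand were a looser filter (200 genes, 20% mitochondrial UMIs), a stricter filter (1000 genes, 5%), no doublet removal, resolutions 0.5 and 2, clustering each library alone, median-of-ratios and trimmed-mean scaling, equal weight per cell, removal of free RNA, minimums of 10 and 200 UMIs, no filter on other classes and a pseudocount of 10 CPM. Alternatives added after the data were seen were the first naming rule, parts of the endothelial, fibroblast and astrocyte classes, genes at their highest in the class, and genes of which no cell held over 25% of the UMIs in the library where the gene was higher. Software was Python 3.11.15 with anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9.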

Results

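The libraries profile the cells of brain vessels and borders together with the brain's macrophages in adult mice. The control library came from Csf1rfl/fl mice, in which the gene for the colony-stimulating factor 1 receptor carries loxP sites. The mutant library came from Mrc1Cre:Csf1rfl/fl mice, in which Cre recombinase from the Mrc1 locus acts on those sites in cells that express the mannose receptor, a marker of border-associated macrophages (BAMs). By its title the study asks how perivascular macrophages that depend on interleukin-34, a CSF1R ligand, serve the vessels of the brain. The control matrix held 8739 barcodes with 85716531 UMIs and a median of 7998 UMIs per barcode. The mutant matrix held 8735 barcodes with 82806348 UMIs and a median of 8236. After filters and doublet removal 5607 control and 6139 mutant cells remained, of which 4933 and 5142 were named. There was 1 library per genotype, so every difference below describes these 2 libraries and could not be set against a spread between animals.

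Microglia-like cells were the largest class and had close shares in both libraries, 58.7% of named cells in the control and 56.3% in the mutant. BAM-like cells, the resident macrophages of perivascular spaces, meninges and choroid plexus, were fewer in the mutant, at 122 cells or 2.37% (95% interval 1.97 to 2.83) against 312 cells or 6.32% (5.66 to 7.04) in the control. Among BAM-like plus microglia-like cells, the BAM-like share was 9.72% (8.72 to 10.8) in the control and 4.04% (3.37 to 4.81) in the mutant. BAMs and microglia were sorted through separate gates, so this share also follows how much of each gate was loaded. Astrocyte-like cells made up 13.5% of control and 4.69% of mutant named cells, fibroblast-like cells 3.69% and 9.53%, endothelial-like cells 2.57% and 3.62%, and choroid plexus epithelium-like cells 12.9% and 20.8%. Under the first naming rule, which left astrocyte clusters 5 and 7 and the choroid plexus epithelium unnamed, astrocyte-like cells were 1.26% of control and 1.15% of mutant named cells. These shares also follow how much of each gate was loaded, and the labels give no gate for choroid plexus epithelium. Oligodendrocyte-like, ependymal-like and erythroid-like cells each stayed below 2% in both libraries.

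**Figure D1:**
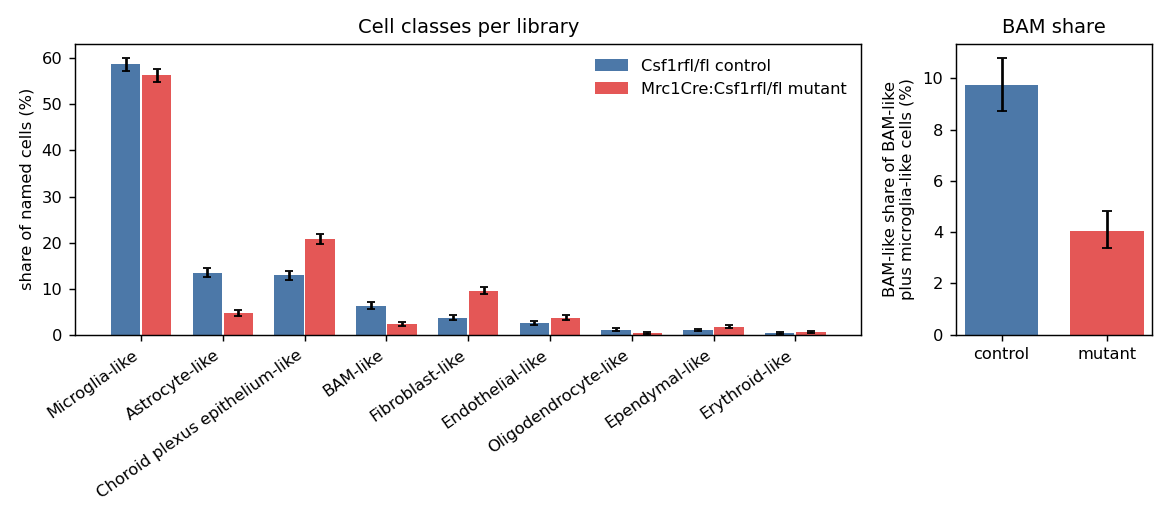
Bars give the share of each named class among named cells in percent (left) and the BAM-like share of BAM-like plus microglia-like cells in percent (right), for the control (blue) and mutant (red) library, with exact Clopper-Pearson 95% intervals as error bars. The BAM-like share of macrophages was 9.72% in the control and 4.04% in the mutant, while microglia-like cells made up 58.7% and 56.3% of named cells.

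Unnamed clusters held 674 of the 5607 kept control cells and 997 of the 6139 kept mutant cells. The largest, cluster 12, was a shallow cluster without a microglial marker among its leading genes and held 9.54% of control and 12.3% of mutant kept cells. Cluster 10 was led by H2-Eb1, H2-Aa, Ccr2 and Plac8, genes of monocytes and dendritic cells, with 60 control and 71 mutant cells. Cluster 20, with 16 control and 29 mutant cells, carried the pericyte genes Rgs5, Kcnj8 and Abcc9 beside microglial markers. No cluster could be named pericyte-like or smooth muscle-like under the main or any alternative setting, so no comparison of these classes and no smooth muscle share of mural cells was possible.

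Csf1r (ENSMUSG00000024621, chromosome 18, 61100598 to 61132149, plus strand, GRCm38), the receptor that maintains macrophages and microglia, was the targeted gene. In BAM-like cells it stood at 1444 CPM (1404 to 1484) in the control and 1187 CPM (1126 to 1251) in the mutant, a ratio of 0.822 (0.774 to 0.873). In microglia-like cells it stood at 2358 CPM (2341 to 2376) and 1877 CPM (1862 to 1893), a ratio of 0.796 (0.787 to 0.805). The UMIs are read at the 3′ end of the transcript, which can lie outside the deleted part, so these levels do not check the deletion. Csf1r UMIs were also found in other classes. They were higher in the mutant in endothelial-like (334 and 443 CPM) and astrocyte-like cells (81.8 and 123 CPM). They were lower in fibroblast-like (148 and 94.8 CPM), choroid plexus epithelium-like (41.6 and 21.5 CPM) and ependymal-like cells (104 and 62.9 CPM). In all of these classes except endothelial-like cells, Csf1r fell under the filter on other classes, so these UMIs may be free RNA. In endothelial-like cells the microglial transcripts C1qa, C1qb and Ctss were higher in the mutant too. Whether any of these classes expressed Csf1r itself was not tested.

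Il34 (ENSMUSG00000031750, chromosome 8, 110741829 to 110805924, minus strand) was concentrated in a pair of small clusters. In the pericyte-marked cluster 20 it reached 221 CPM in the control (20 UMIs) and 116 CPM in the mutant (19 UMIs). Other genes of that cluster differed as well, with the pericyte genes Pdgfrb at 1061 and 323 CPM, Kcnj8 at 719 and 146 CPM and Rgs5 at 3018 and 798 CPM, and Csf1r at 1050 and 1632 CPM. In fibroblast cluster 21 it reached 153 CPM and 133 CPM, against 7.48 CPM and 8.94 CPM in the larger fibroblast cluster 11. Microglia-like and BAM-like cells held at most 6 Il34 UMIs per library. Over all fibroblast-like cells Il34 was lower in the mutant (82 control and 130 mutant UMIs, CPM ratio 0.560, 0.422 to 0.748), while within clusters 11 and 21 its ratios were 1.20 (0.640 to 2.40) and 0.870 (0.623 to 1.22). Csf1 (ENSMUSG00000014599, chromosome 3, 107741048 to 107760469, minus strand), the other ligand, stood at 100 CPM in the control and 114 CPM in the mutant in microglia-like cluster 2, and at 104 and 87.7 CPM in oligodendrocyte-like cells. In endothelial-like cells Csf1 stood at 14.9 and 47.1 CPM, with 8 and 34 UMIs, too few to enter the size rule.

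In BAM-like cells Ccl8 (ENSMUSG00000009185, chromosome 11, 82115185 to 82116799, plus strand), a monocyte-attracting chemokine, stood at 641 CPM in the mutant against 100 CPM in the control, a ratio of 6.39 (5.62 to 7.28). Cd163 (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527, plus strand), the haemoglobin scavenger receptor, stood at 225 CPM (199 to 254) against 566 CPM (541 to 591), a ratio of 0.398 (0.349 to 0.453). The C-type lectins Cd209a and Cd209b, with 252 and 139 UMIs in the control, had 0 UMIs in the mutant and were at least 28.0-fold and at least 15.4-fold lower. Their control UMIs lay in 54 and 52 of 312 cells. Cd209a was also among the markers fixed for monocytes or dendritic cells, so it may mark a part of the control cells. The chemokine Ccl2 was higher at a ratio of 2.90 (2.43 to 3.48), as were the lectin Clec4b1 at 44.5 against 6.85 CPM, Lilrb4b at 4.61 (3.06 to 7.01), the heparanase gene Hpse at 3.97 (2.49 to 6.39) and the growth factor Pdgfc at 3.91 (2.72 to 5.64). Cacna1a, Gramd1b, Fyn and Iigp1 completed the highest 10 genes with ratios from 2.73 to 4.35, and for Iigp1 1 cell held 25.2% of the mutant UMIs. Gimap6, Rad51b, Ptprk, Cenpf, H4f16 and Igf2bp3 completed the lowest 10 beside Prl, with ratios from 0.205 to 0.347.

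**Figure D2:**
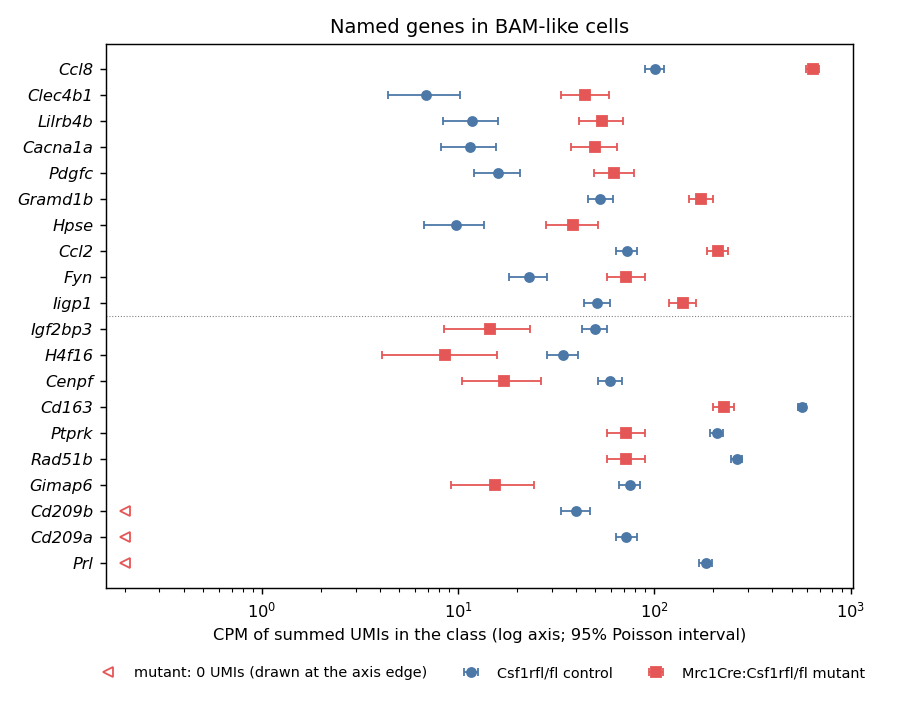
Points give the CPM (log axis) of summed UMIs in BAM-like cells for the 10 genes with the highest (above the dotted line) and the 10 with the lowest ratio in the control (blue circles) and mutant (red squares) library, with exact Poisson 95% intervals, and open triangles at the axis edge mark 0 UMIs. Ccl8 stood at 100 CPM in the control and 641 CPM in the mutant, Cd163 at 566 and 225 CPM.

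Of 7575 genes in the rule, 211 met it as higher and 188 as lower in BAM-like cells, a description of these 2 libraries, while trimmed-mean scaling gave 181 and 229, the stricter filter 191 and 262 and equal weight per cell 415 and 411. In simulated BAM-like counts, without the filter on other classes, counting error alone made 150 unaltered genes meet the rule. All 6 measured MHC class II genes, which present peptides to CD4 T cells, were higher, with a median log2 ratio of 0.90 above all 10000 random lists. H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419, plus strand) stood at 834 against 378 CPM, a ratio of 2.21 (2.03 to 2.40), Cd74 at 2.04 (1.94 to 2.15), H2-Aa at 1.91 (1.77 to 2.06) and H2-Eb1 at 637 against 349 CPM. With each library clustered alone the median was 1.56, and the medians were -0.41 for BAM identity and 0.71 for homeostatic microglial genes. The level was uneven between cells: summed over the list it had a median of 436 CPM and a 90th percentile of 18043 CPM per cell in the mutant, against 147 and 3434 CPM in the control. More than 2000 CPM, a level chosen after the data were seen, was found in 37 of 122 mutant cells, or 30.3% (22.3 to 39.3). In the control it was found in 40 of 312 cells, or 12.8% (9.32 to 17.0). Of the 13 measured genes of cholesterol synthesis and uptake, 9 were lower, 0 higher and 4 neither, with a median of -0.73 below all random lists, and for 6 of the 13 another class had at least 10-fold higher levels. Lower members were Fdft1 at a ratio of 0.382 (0.147 to 0.840), Hmgcs1 (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260, plus strand) at 0.480 (0.283 to 0.773) and Msmo1 at 0.553 (0.393 to 0.763). Of the 20 genes of BAM identity, 4 were lower, 2 higher and 14 neither, with a median of -0.16 at percentile 0.03. Cd163 and the lectin Cd209f (0.481, 0.422 to 0.546) were on the lower side, and the sialoadhesin gene Siglec1 (131 against 65.4 CPM) and the folate receptor Folr2 (1.92, 1.77 to 2.09) on the higher side. Mrc1, whose locus drives the Cre and which was named after its values were seen, stood at 4583 CPM in the control and 3413 CPM in the mutant.

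The immediate early genes, which respond to cell isolation as well as to signals in tissue, had 7 of 21 members lower, 0 higher and 14 neither in the mutant BAM-like cells, and a median of -0.42 below all random lists. Ccn1 stood at a ratio of 0.466 (0.293 to 0.713), Btg2 at 0.508 (0.428 to 0.599), Zfp36 at 0.596 (0.490 to 0.720) and Fos at 0.621 (0.526 to 0.731). Type I interferon genes had 4 of 20 members higher and 1 lower, with a median of 0.31, above all random lists. Rsad2 was at a ratio of 2.12 (1.61 to 2.78), Oas1a at 1.93 (1.17 to 3.15) and Ifit2 at 1.67 (1.26 to 2.19), while Gbp2 was at 0.207 (0.0545 to 0.559), and 1 cell held 34.0% of the mutant Rsad2 UMIs and 1 cell 38.8% of the mutant Ifit2 UMIs. Glycolysis and hypoxia genes lay above their random lists (median 0.23, percentile 98.9, Bnip3 at 1.66), and cell cycle genes (-0.54, percentile 0.10, Cenpf at 0.287) and mitochondrially encoded genes (-0.13, percentile 0.85) below. Of 11 chemokine and cytokine genes, 3 were higher and 0 lower, namely Ccl2, Ccl12 at 2.12 (1.95 to 2.30) and Ccl7 at 1.91 (1.61 to 2.27). The 9 lists that did not stand apart in BAM-like cells, the chemokine and cytokine genes, homeostatic microglial genes (median 0.03) and scavenging and iron handling (-0.08) among them, had medians from -0.08 to 0.43.

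Of 9369 genes in the rule, 58 met it as higher and 95 as lower in microglia-like cells, the fewest among the 5 sorted classes compared. With genes below 10% of their CPM in another class counted in, 685 genes met it in microglia-like cells, 159 as higher and 526 as lower, against 700 in fibroblast-like, 582 in astrocyte-like, 520 in endothelial-like and 510 in BAM-like cells. The genes of homeostatic microglia all lay within 1.5-fold, 0 of 18 higher or lower, with a median of -0.06 at percentile 0.73. The largest differences among them were Sall3 at a ratio of 1.27 (1.22 to 1.32), Csf1r at 0.796, the fractalkine receptor gene Cx3cr1 at 0.822 (0.808 to 0.835) and the purinergic receptor gene P2ry13 at 0.839 (0.821 to 0.856). The chemokine genes Ccl3 and Ccl4 were lower, at 24.7 against 54.2 CPM and at 48.5 against 103 CPM. The chemokine receptor gene Ccr2, a monocyte marker, was higher at 3.16 (2.69 to 3.72) but stood at only 6.85 and 21.7 CPM. Naalad2, Gdpd3, the B-cell survival factor Tnfsf13b, Eps8l1, Arsg, Klk8, Pxdc1, Cd34 and Wdr41 completed the highest 10, with ratios from 1.65 to 2.34. Nbea at 0.254 (0.237 to 0.271), Dlc1 at 0.322 (0.301 to 0.344), Gpr165, Glis3, Cd79b, the phosphatase gene Ptprm and the ubiquitin gene Ubb at 0.595 (0.566 to 0.625) were among the lowest.

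Immediate early genes in microglia-like cells had 4 of 21 members lower, 0 higher and 17 neither, and a median of -0.23 below all random lists, led by Fosb at 0.233 (0.161 to 0.330) and Fos at 0.495 (0.379 to 0.643). For 12 of these 21 genes another class had at least 10-fold higher levels. Inflammatory cytokines had 2 of 14 lower and a median of -0.12 at percentile 1.74. Nuclear genes of oxidative phosphorylation lay slightly above (median 0.06, percentile 99.2) and mitochondrially encoded genes slightly below their random lists (-0.09, percentile 0.50), with 0 members of either list beyond 1.5-fold. Of the 20 genes of disease-associated microglia, 2 were higher and 4 lower, with a median of -0.02. The osteopontin gene Spp1 stood at 0.271 (0.234 to 0.313), lipoprotein lipase Lpl at 0.592 (0.545 to 0.643) and dectin-1 gene Clec7a at 1.58 (1.44 to 1.72), and 1 cell held 53.0% of the control Spp1 UMIs. MHC class II had 2 of 6 lower and a median of 0.01, and type I interferon genes had 0 of 20 members beyond the rule. The 10 lists that did not stand apart in microglia-like cells, these last ones among them, had medians from -0.18 to 0.01.

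In endothelial-like cells Plvap (ENSMUSG00000034845, chromosome 8, 71497765 to 71511752, minus strand), the diaphragm protein of fenestrated vessels, stood at 112 CPM (89.1 to 139) in the mutant against 640 CPM (574 to 712) in the control, a ratio of 0.175 (0.136 to 0.224). A Plvap UMI was found in 9 of 186 mutant and 19 of 127 control cells, and after thinning to 2000 UMIs per cell in 5.30% and 17.0%, with 54 mutant and 27 control cells too shallow. The same share in microglia-like cells, which should lack the gene, was 0.285% and 0.249%. Lower too were the retinol-binding protein gene Rbp7 at 0.0659 (0.0276 to 0.136), Col13a1 at 0.120 (0.0547 to 0.235), the elastin gene Eln at 0.198 (0.106 to 0.348), Fam167b, Ldb2, Plpp1 at 0.264 (0.221 to 0.315), Prss23 and Rgcc at 0.322 (0.271 to 0.381). For Rbp7 and Eln 1 cell held 63.3% and 41.7% of the control UMIs, while Rgcc UMIs were found in 70 control and 75 mutant cells with at most 9.98% of the control UMIs in 1 cell. In cells without a Plvap UMI, Rgcc stood at 313 CPM in the control and 196 CPM in the mutant (0.625, 0.488 to 0.801), Plpp1 at 0.767 (0.534 to 1.11), Prss23 at 0.479 (0.312 to 0.730) and Eln at 0.144 (0.0674 to 0.282), and Rbp7 at 0 CPM in both libraries. Among the 10 highest genes were C1qa, C1qb, C1qc, Selplg, Ly86, Plxdc2, Gna15, Ctss and Ctsd at ratios from 1.95 to 3.71, most of them microglial transcripts. Among genes at their highest in endothelial-like cells, a choice made after the data were seen, 15 were higher and 50 lower. The Rac activator Tiam1 at 1.79 (1.33 to 2.42) and Tecpr1 at 1.86 (1.26 to 2.81) led the higher ones.

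In all, 257 of 4782 genes met the rule as higher and 206 as lower, while trimmed-mean scaling gave 313 and 157 and the data without doublet removal 164 and 253, and the stricter filter 145 and 126. The 21 barrier transporters had 0 members beyond the rule and a median of 0.06 (percentile 88.5), with Mfsd2a at 0.748 (0.567 to 0.987) and Slc38a3 at 1.33 the farthest apart. Junction genes had 1 of 12 lower (Cdh5 at 0.662, 0.552 to 0.793) and a median of -0.08, and Wnt target genes 0 of 17 with 0.06. Extracellular matrix genes had 6 of 16 lower, 0 higher and a median of -0.40 below all random lists, with Col15a1 at 0.303 (0.170 to 0.519) and the metalloprotease inhibitor Timp3 at 0.409 (0.352 to 0.475). RNA of mural cells was found in the same class, with 27 control and 0 mutant UMIs of Acta2, 8 and 2 of Pdgfrb and 4 and 3 of Kcnj8, while Rgs5 stood at 0.845 (0.658 to 1.09) and in cells without a Plvap UMI at 0.369 (0.268 to 0.506), and these genes were named after their values were seen. Angiogenesis genes had 4 of 11 lower and a median of -0.24 at percentile 1.95, with Esm1 at 0.398 (0.269 to 0.581) and Kdr, a receptor for VEGF, at 0.647 (0.573 to 0.730). In cells without a Plvap UMI their median was -0.11, with Kdr at 0.911 (0.777 to 1.07) and Esm1 at 0 CPM in the mutant and 2.37 CPM in the control. Arterial genes had 2 of 6 lower, 1 higher and a median of -0.51 at percentile 0.22, with Mgp at 0.224 (0.175 to 0.286), Gkn3 at 0.371 (0.229 to 0.589) and Alpl at 2.06 (1.26 to 3.48), and 1 cell held 98.3% of the control Gkn3 UMIs and 1 cell 52.2% of the control Mgp UMIs. Venous, vascular tone and capillary genes did not stand apart. Of 7 venous genes (median -0.13, percentile 22.9) 3 were lower, Vwf at 0.331 (0.241 to 0.449), Il1r1 at 0.400 (0.267 to 0.592) and Nr2f2 at 0.494 (0.311 to 0.778). Of 7 vascular tone genes (-0.12, percentile 25.6) 3 were lower, the endothelin receptor Ednrb at 0.271 (0.151 to 0.466), Gja1 and Edn1, and of 9 capillary genes (-0.07, percentile 22.4) 1 was lower. In cells without a Plvap UMI the medians were -0.13 for matrix, -1.03 for arterial, -0.80 for venous, -0.25 for capillary and -0.09 for barrier transporter genes. Immediate early genes (median -0.26, percentile 0.78, Dusp1 at 0.484), MHC class I (-0.28, percentile 1.65) and nuclear oxidative phosphorylation (-0.24, percentile 0.20) also lay below their random lists. Under the stricter filter the median of the immediate early genes was 0.00129. MHC class I had 0 of 9 members lower and 1 higher, and its median was -0.04 in cells without a Plvap UMI. Oxidative phosphorylation had 0 of 21 lower and 0 higher, and its median was 0.18 without doublet removal. The 14 lists that did not stand apart had medians from -0.27 to 0.24.

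Fibroblast-like cells formed a pair of clusters whose mix differed: cluster 11 held 74.7% of control and 88.0% of mutant fibroblast-like cells, and cluster 21 the rest. Marker support differed as well. Cluster 21 carried 10 of 10 fibroblast markers, with 5 among its leading 10 genes, and cluster 11 carried 3 of 10, with 0 among its leading genes, which began with Mgp, Ccn3 and Slc47a1. Over the class, 180 of 9330 genes met the rule as higher and 242 as lower, in cluster 11 alone 176 and 135, and with equal weight per cell 277 and 370. The transporter genes of brain fibroblasts were lower, 7 of 11 with 0 higher and a median of -0.84 below all random lists. Slc6a13 (ENSMUSG00000030108, chromosome 6, 121300227 to 121337733, plus strand), a GABA and taurine transporter, stood at 46.7 against 219 CPM, a ratio of 0.213 (0.183 to 0.247), Slc22a6 at 0.278 (0.209 to 0.368), the cystine transporter Slc7a11 at 0.341 (0.309 to 0.377) and Slc13a4 at 0.356 (0.279 to 0.453). These genes sat mainly in cluster 21, where Slc6a13 was 480 against 1066 CPM (0.450, 0.388 to 0.522) and Slc7a11 1268 against 1763 CPM (0.719, 0.650 to 0.796), and the list's median within cluster 11 was 0.02. Of 8 measured immune mediators 4 were lower and 0 higher (median -0.55), with the chemokine Ccl19 at 0.273 (0.186 to 0.400) and complement C4b at 0.411 (0.297 to 0.570), and the median within cluster 11 was -0.19. Of 31 matrix genes 8 were lower and 2 higher (median -0.19, below all random lists), with Lum at 0.405 (0.349 to 0.470) and Col15a1 at 0.415 (0.345 to 0.499), and the median within cluster 11 was -0.04.

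The immediate early genes in fibroblast-like cells had 9 of 19 members lower, 0 higher and 10 neither, with a median of -0.45 below all random lists, and their median within cluster 11 was -0.40. Within cluster 11 Egr1 stood at 18.6 against 122 CPM (0.152, 0.119 to 0.194), Fos at 0.214 (0.157 to 0.291), Nr4a1 at 0.331 (0.239 to 0.460) and Dusp1 at 0.339 (0.285 to 0.404). Type I interferon genes had 3 of 19 higher and 1 lower with a median of 0.27 at percentile 99.97, and Ifi27l2a stood at 1.99 (1.71 to 2.32) and Ifit1 at 1.71 (1.34 to 2.20). Lypd2 at 3.43 (2.62 to 4.56), Dapl1 at 6.81 (3.22 to 17.3) and the lubricin gene Prg4 at 338 against 169 CPM were also higher. The bone genes Bglap at 62.7 (41.7 to 99.0), Bglap2 and Bglap3, with Car3, Angptl1 and the collagen gene Col1a1 at 2.29 (2.19 to 2.38), were higher, and in cluster 21 2 cells held 90% of the mutant Bglap UMIs and 2 cells 90% of the mutant Col1a1 UMIs. In cluster 11 2 cells held 90% of the mutant UMIs of Top2a, the gene that led the cell cycle list (5 of 9 higher, median 0.88), and for 7 of these 9 genes another class had at least 10-fold higher levels. The median of the cell cycle list was 0.063 with each library clustered alone and -0.045 under the looser filter. Among the lowest genes, Vtn stood at 0.132 (0.121 to 0.144), Aldh1a2 at 0.217 (0.168 to 0.279) and Chad at 0.213 (0.166 to 0.272), with Tagln, Ifitm1, Cmbl and Sidt1, and 1 cell held 83.7% of the control Tagln UMIs and 1 cell 35.8% of the control Chad UMIs. Cluster 21 held 1881 of 1887 control and 506 of 703 mutant Vtn UMIs, at 4176 and 843 CPM there. Vtn was also among the pericyte markers and Tagln among those of smooth muscle. Whether the cluster mix or RNA of mural cells contributed was not tested. The 8 lists that did not stand apart had medians from -0.05 to 0.13.

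Astrocyte-like cells came from clusters 5, 7 and 18, and cluster 7 held 64.2% of control and 66.8% of mutant cells, cluster 5 30.7% and 22.4%, and cluster 18 5.12% and 10.8%. Reactive astrocyte genes lay above their random lists, 4 of 9 higher and 0 lower with a median of 0.53 at percentile 99.98. The iron oxidase Cp stood at 2.92 (1.62 to 5.22), H2-D1 at 30.5 against 15.2 CPM, C4b at 20.3 against 10.1 CPM and Srgn at 1.97 (1.16 to 3.26). For 6 of these 9 genes another class had at least 10-fold higher levels, 1 cell held 37.5% of the mutant Cp UMIs, and the median within cluster 7 was 0.27. The free RNA share estimated for astrocyte-like cells was 6.80% in the control and 12.7% in the mutant, and with free RNA removed the median of the list was 0.38. End-foot genes, which anchor astrocytes to vessels, had 0 of 13 members beyond the rule and a median of 0.02, with the angiotensinogen gene Agt at 1.19 (1.12 to 1.27) and Mlc1 at 1.17 (1.06 to 1.29). Genes of glutamate uptake and metabolism had 0 of 17 beyond it, with Slc1a3 at 1.31 (1.27 to 1.35) and Slc1a2 at 0.804 (0.787 to 0.822). Cholesterol synthesis (-0.10, percentile 0.71), nuclear oxidative phosphorylation (-0.10, percentile 0.32) and mitochondrially encoded genes (-0.11, percentile 1.48) lay slightly below their random lists with 0 members beyond the rule, and their medians were above 0 in cluster 7. Immediate early genes had 1 of 11 higher and 0 lower, with a median of 0.06 at percentile 58.3.

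In astrocyte-like cells 224 of 9200 genes met the rule as higher and 125 as lower, while trimmed-mean scaling gave 159 and 178, median-of-ratios scaling 185 and 161 and the stricter filter 435 and 274. The ion channel gene Kcnj3 at 2.81 (2.40 to 3.28), the kinase gene Prkg1 at 2.70 (2.43 to 3.01), the splicing factor gene Rbfox1 at 469 against 188 CPM, the AMPA receptor gene Gria4 at 1.98 (1.89 to 2.08), Greb1l, Mybpc1, Cadps2, Ust and Tnc were among the highest 10. Gria4 was carried by cluster 18, at 5538 CPM in the control and 8830 CPM in the mutant, and stood at 599 and 484 CPM in cluster 7. Kcnj3, Mybpc1 and Tnc were, like Gria4, among the leading 10 genes of cluster 18. Within cluster 7 the ratio was 1.94 (1.41 to 2.66) for Kcnj3, 1.39 (1.03 to 1.84) for Prkg1, 1.22 (1.01 to 1.49) for Rbfox1 and 0.896 (0.599 to 1.31) for Ust. Sgcz (ENSMUSG00000039539, chromosome 8, 37522298 to 38661508, minus strand) had the highest bound, at 4.67 (3.55 to 6.16), but 1 cell held 77.5% of its mutant UMIs. Among the lowest were the forebrain transcription factor gene Emx2 at 0.353 (0.208 to 0.568), the netrin receptor gene Dcc at 0.498 (0.417 to 0.590), Swap70, Lama3, Zfand4, Unc13c, Lypd6, Trp63 and the GDNF receptor gene Gfra1, with ratios from 0.353 to 0.582. The 7 lists that did not stand apart had medians from -0.11 to 0.25.

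Prl, the pituitary hormone prolactin, was the lowest gene or among the lowest in each class because its UMIs occurred in the control library alone. All control barcodes together held 142194 Prl UMIs, of which 113094 lay in the 45 control cells of cluster 3, a neuron-marked unnamed cluster, and 4 of those cells held 90% of them. The mutant library held 0. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were higher in the mutant library. The sex-linked list held 5 genes, of which 4 were measured in microglia-like, fibroblast-like and astrocyte-like cells. Its medians there were 1.19, 0.91 and 0.73. In BAM-like cells 0 of 3 measured members met the rule and the median was 0.43 at percentile 93.1.

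**Figure D3:**
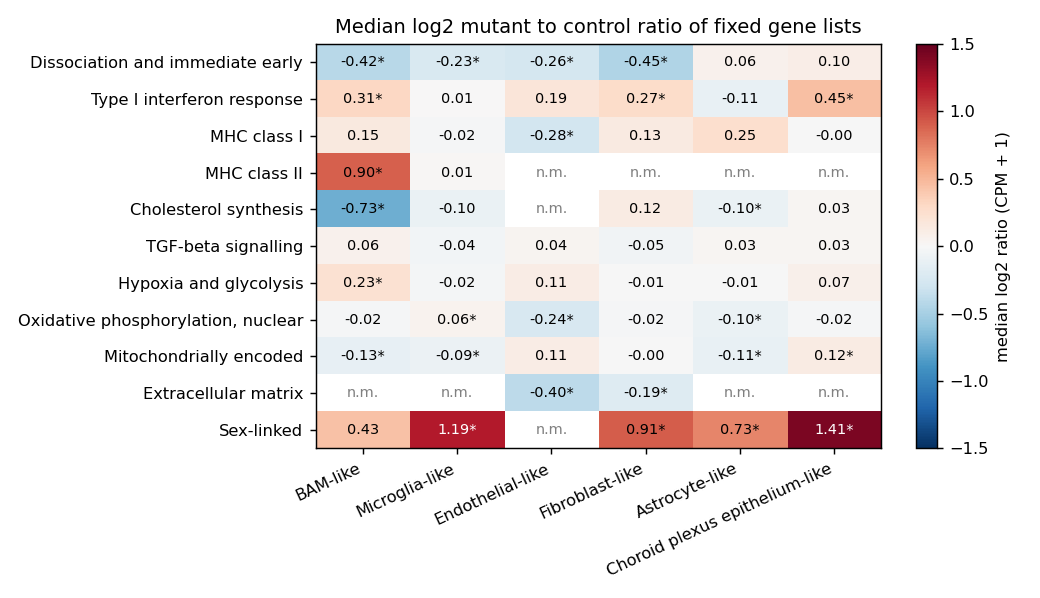
Cells give the median log2 ratio (CPM plus 1) of mutant to control over the measured members of fixed gene lists (vertical axis) in each class (horizontal axis), with red for higher and blue for lower in the mutant, n.m. for under 3 measured members, and a star for medians outside the middle 95% of 10000 matched random lists. MHC class II stood at 0.90 and cholesterol synthesis at -0.73 in BAM-like cells, and immediate early genes at -0.42, -0.23, -0.26 and -0.45 in BAM-like, microglia-like, endothelial-like and fibroblast-like cells and at 0.06 and 0.10 in astrocyte-like and choroid plexus epithelium-like cells.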

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

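The tests of gate loading, of dilution by microglial RNA and of monocyte or dendritic cells were chosen only after the results were seen, and the last of them replaced a test on a pair of markers that had too few UMIs.

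Clusters left unnamed held cells outside every comparison. All of them took a larger share of the mutant than of the control library, and for the 4 given here the intervals of the shares did not overlap. Cluster 3, with the neuronal genes Syt1 and Snap25, held 1.35% of mutant and 0.803% of control kept cells. Cluster 12, shallow cells with microglial markers and the leading genes Lysmd4 and Gm26992, held 12.3% and 9.54%. Cluster 22, with the genes of young neurons Sox11, Stmn2 and Dcx, held 0.521% and 0.125%. Cluster 23, with the hair-cell genes Ptprq, Xirp2 and Loxhd1, held 0.163% of mutant cells (0.0781 to 0.299) and 0 control cells (0 to 0.0658%). No explanation was tested for these clusters.

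The BAM-like share of macrophages was lower in the mutant library. Naming of clusters was argued against only for cells that kept their BAM markers. With no cluster used, the share of kept cells with at least 4 BAM markers after thinning to 3000 UMIs had a mutant to control ratio of 0.381 (0.304 to 0.475). The markers were those that named the class, so cells that had lost them would be missed here too. The share was taken over all kept cells, so it also follows gate loading. Loss to the filter was argued against only for barcodes with that depth, where the ratio was 0.390 (0.315 to 0.480) and the same limits hold. Shallower barcodes, 1792 in the control and 1883 in the mutant, were left out, so a loss of shallow BAMs to the filter stays open. The amount loaded from the BAM gate against the microglial gate and a loss of BAMs in the mutant cannot be told apart, because the number of microglia-like cells was alike (ratio 0.9997, 0.949 to 1.05) and nothing in the values used here records what each gate contributed. An effect of the Csf1r deletion in Mrc1-expressing cells may explain the lower share, and with 1 library per genotype it was not tested.

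Endothelial genes, Plvap and Vwf among them, were lower in the mutant library. Over Plvap and 48 other such genes the median log2 ratio was -0.91 (-1.06 to -0.81). These genes were chosen for being lower in these cells, so the sign of that median was set by the choice. Dilution by microglial RNA was argued against, because it would lower the barrier transporters too and their median was 0.065 (-0.0043 to 0.13). Fewer Plvap-bearing cells may explain part of the lower levels and stay open. In cells without a Plvap UMI the median of the 48 genes without Plvap was -0.61 (-0.72 to -0.47), between the bounds set for and against it. Most cells of the class remained, so the choice of lower genes favoured a negative median here too. The genes also differed. In these cells control Esm1 stood at 2.37 CPM against 153 CPM over the class and Igfbp3 at 4.74 against 312 CPM. Vwf kept a ratio of 0.275 (0.200 to 0.373) and Il1r1 of 0.347 (0.229 to 0.518). Pituitary tissue in the control library could bring fenestrated vessels and stays open although the bound set beforehand was met, with Prl CPM in control cells with Plvap at 0.491 (0.283 to 0.806) of that in cells without. That bound was wrong because Prl per droplet was alike in both, at 0.947 and 1.26 UMIs per cell (ratio 0.752, 0.433 to 1.23), so that the test read free RNA. An effect of the genotype on vessels stays open and was not tested.

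MHC class II genes were higher in BAM-like cells of the mutant library. Free RNA was argued against, with a median log2 ratio of 0.93 (0.87 to 1.03) after its removal. A shift between Lyve1-positive and Lyve1-negative cells was argued against, since the smaller of the medians within them was 0.72 (0.57 to 0.79) and the Lyve1-positive share was 68.6% and 68.0%. The bound set beforehand, 0.58, was narrowly missed by that interval, which stayed above the 0.3 that the shift would allow. By that bound alone the shift would stay open. The reading against it rests on 0.3 and on the alike shares, a criterion added after the results were seen. Monocytes or dendritic cells with the Ccr2 and Plac8 levels of cluster 10 were argued against within the class. They would need to give 12.5% of its UMIs, which would bring this pair of genes to 184 CPM. The level found was 10.3 CPM, or 5.59% (2.89 to 9.77) of that. Clustering had already placed cells rich in these genes in cluster 10, so a low level here was likely beforehand. In cluster 10 Ccr2 was found in 61.8% and Plac8 in 37.4% of cells, so such cells without these genes stay open. Plac8 had 0 control and 6 mutant UMIs and Ccr2 35 and 6. Of the other monocyte or dendritic markers, Cd209a had 252 control and 0 mutant UMIs. Ly6c2, Chil3, Flt3 and Xcr1 had at most 3 per library. A response of some of the remaining BAMs may be at work, a hypothesis that was found on these data and was not tested. A change in the mix of BAMs with high and low levels stays open and was not tested. BAM-like cells with more than 2000 CPM of these genes numbered 40 in the control and 37 in the mutant, of 312 and 122 cells. Cell numbers also follow gate loading, so they do not decide between these readings.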

How the results depend on the processing

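The first naming rule, the parts of the endothelial, fibroblast and astrocyte classes, the genes at their highest in a class and the genes spread over cells were alternatives chosen only after the data were seen. The BAM-like share of macrophages was lower in the mutant than in the control library under every setting run. Of 84 comparisons of shares, 51 stayed within the counting interval and 33 moved. Of 81 counts of genes that met the size rule, 64 stayed within 1.5 times the count reported and 17 moved. Of 987 list medians 845 stayed within their interval, 129 moved and 13 reversed. MHC class II in BAM-like cells had a median of 0.90, of 1.35 with equal weight per cell and of 1.56 with each library clustered alone. No paired analysis was possible because each genotype had 1 library.

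For the shares that a filter, the doublet removal or separate clustering moved, the cause was not tested. Under the looser filter the BAM-like share of macrophages was 11.6% in the control and 5.07% in the mutant, and class shares in the control and mutant were 11.8% and 3.13% for astrocyte-like, 3.19% and 4.28% for endothelial-like and 50.5% and 46.8% for microglia-like cells, with 4.59% for control fibroblast-like cells. Under the stricter filter the control BAM-like share of macrophages was 6.99%. Class shares were then 5.20% and 2.48% for astrocyte-like, 2.08% and 2.51% for endothelial-like, 0.761% and 1.13% for fibroblast-like and 81.0% and 84.6% for microglia-like cells, and 3.25% for mutant BAM-like cells. Without doublet removal the control BAM-like share was 7.14% of named cells and 11.04% of macrophages. With each library clustered alone the mutant shares were 2.85% for BAM-like and 53.4% for microglia-like cells, and 5.06% for BAM-like cells among macrophages. Under the first naming rule, which left more clusters unnamed, control and mutant shares were 1.26% and 1.15% for astrocyte-like, 8.72% and 3.27% for BAM-like, 3.55% and 4.99% for endothelial-like and 81.0% and 77.6% for microglia-like cells, with 11.6% for mutant fibroblast-like cells.

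Counts of genes that met the size rule were lower with at least 200 UMIs and among genes at their highest in the class, which test fewer genes. With at least 200 UMIs they were 123 in astrocyte-like, 142 in BAM-like, 85 in endothelial-like, 157 in fibroblast-like and 86 in microglia-like cells, and among genes at their highest in the class 54, 71, 65, 97 and 18. Without the filter on other classes, which adds genes, they were 582 in astrocyte-like, 700 in fibroblast-like and 685 in microglia-like cells. Equal weight per cell gave 826 in BAM-like and 647 in fibroblast-like cells, and the stricter filter 709 in astrocyte-like and 271 in endothelial-like cells, and the cause was not tested. Fibroblast-like cells gave no value under the stricter filter, astrocyte-like cells none under the first naming rule, and cluster 21 alone gave no count, because fewer than 50 cells were left in a library.

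For the reversed list medians the cause was not tested. Under the stricter filter the medians in astrocyte-like cells were 0.21 for cholesterol synthesis, 0.24 for mitochondrially encoded and 0.47 for oxidative phosphorylation genes, and that of immediate early genes in endothelial-like cells was 0.00129. In astrocyte cluster 7 alone the same 3 lists stood at 0.028, 0.081 and 0.056, and in fibroblast cluster 11 alone, which is the fibroblast-like class of the first naming rule, the transporters stood at 0.023. Cell cycle genes in fibroblast-like cells were at -0.045 under the looser filter. Mitochondrially encoded genes in BAM-like cells were at 0.069 with equal weight per cell. Oxidative phosphorylation genes were at 0.18 in endothelial-like cells without doublet removal and at -0.015 in microglia-like cells with free RNA removed. Depth limited the endothelial-like class most, with 535591 control and 722318 mutant UMIs against 29761719 and 29038216 in microglia-like cells.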

Other observations

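All comparisons in this part, those of choroid plexus epithelium-like and ependymal-like cells included, were tests chosen only after the data were seen, and Ttr and Folr1 were named after their values were seen. Choroid plexus epithelium-like cells, which make cerebrospinal fluid, had 62 genes that met the size rule as higher and 37 as lower among 7734. Ttr, the transthyretin gene that dominates this epithelium, stood at a ratio of 0.980 (0.978 to 0.981), and the folate receptor Folr1 at 0.997 (0.975 to 1.02). Type I interferon genes were higher in the mutant, 7 of 15 with 0 lower and a median of 0.45, above all random lists. Ifit1 stood at 3.70 against 0.677 CPM, Isg15 at 4.34 against 0.931 CPM, Irf7 at a ratio of 2.70 (1.59 to 4.81) and Xaf1 at 2.07 (1.44 to 3.04), and for 13 of the 15 genes another class had at least 10-fold higher levels. Pde10a at 2.03 (1.66 to 2.48) was higher, and Ubb at 0.617 (0.591 to 0.645) and Nme2 at 0.553 (0.470 to 0.650) were lower. Dlk1 stood at 8.79 (5.93 to 13.5) with UMIs in 10 mutant and 3 control cells. Mitochondrially encoded genes (median 0.12, percentile 99.97, 1 of 13 higher) and the sex-linked list (median 1.41, 3 of 3 higher) also lay above their random lists. The 7 lists that did not stand apart in choroid plexus epithelium-like cells had medians from -0.09 to 0.10.

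Ependymal-like cells, the ciliated lining of the ventricles, numbered 48 in the control and 88 in the mutant. Nuclear genes of oxidative phosphorylation lay above their random lists with a median of 0.23 at percentile 99.99, 1 of 21 higher and 0 lower, and Atp5g1 stood at 1.55 (1.27 to 1.90). Ctnna3 at 1.94 (1.60 to 2.37), the Notch target Hes1 at 2.24 (1.43 to 3.62) and Kctd16 at 3.51 (1.72 to 8.06) were higher. The cyclin gene Ccnd2 at 0.538 (0.443 to 0.655), the cadherin gene Cdh7 at 0.372 (0.244 to 0.562) and Fgf14 at 0.541 (0.434 to 0.674) were lower.

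Of 7599 genes measured in at least 5 of 6 classes, 6 were lower and 3 higher by at least 0.3 on the log2 scale in every class in which they were measured. The ubiquitin gene Ubb was lower with a median over the classes of -0.72, and Prl was another of the 6. The higher genes were Rplp2 at 0.41 and the Y-linked Ddx3y and Uty, at 0.83 and 0.99 over the 5 classes in which they were measured. Transcripts of tissues outside the sort also differed between the libraries. The pituitary genes Gh and Pomc had 3277 and 4179 UMIs in the control and 2 and 255 in the mutant library. The bone genes Bglap and Ibsp had 74 and 9 UMIs in the control and 4650 and 598 in the mutant, the hair-cell gene Ptprq 24 and 1327, and the olfactory marker Omp 419 and 107.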
